A study of Coturnix japonica with 12 samples.

How the data were processed

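RNA was sequenced from the Müllerian ducts, the embryonic tubes from which the oviduct forms, of female Japanese quail (Coturnix japonica) embryos exposed to sesame oil or to ethynylestradiol (EE), a synthetic oestrogen, between embryonic days 3 and 12. The 12 samples form 4 groups of 3, the left and the right duct under each exposure. Per the labels, total RNA was purified with column kits and libraries were made from polyadenylated RNA. The labels do not say whether replicates of a group came from separate embryos.

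The authors trimmed adapters with cutadapt 1.9.1, aligned reads with HISAT2 2.0.1 and counted them per gene with HTSeq 0.6.1, and their notes also name DESeq2 1.6.3. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. All 16013 genes of the table had the same start and end as in the reference gene table used here. The deposited table holds raw counts per gene for each sample, and the deposited FPKM values (counts scaled by exonic length and by the total counted reads of the sample) were returned from the counts to within 0.005. The exonic gene sizes in the deposited table are lengths in bases, used only in that check. Gene names and descriptions were taken from the table, and 35 genes of the lists were found through their descriptions under a LOC identifier.

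The counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, quasi-likelihood test, two-sided) in a single model of the 12 samples with 4 group means. Genes entered with an FPKM of at least 1 in at least 3 samples of any group, which kept 12113 genes. Before the data were examined the design named limma on log2(FPKM + 1) as the test, to be replaced by edgeR if the table held counts. Comparisons were left minus right in oil, left minus right in EE, EE minus oil in left ducts, EE minus oil in right ducts, and the interaction, which is the left minus right difference in EE minus that in oil. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05. Changes are log2 ratios with their standard error (SE), and expression levels are CPM, the counts scaled to library size and TMM factor by edgeR's cpm function, with the standard deviation (SD) of 3 samples. The adjusted p-values in the text are from edgeR quasi-likelihood unless another tool is named. An exact permutation test of 3 samples against 3 cannot give a p under 0.1, and by chance 10% of genes have groups that do not overlap.

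Genes were named by a rule written before the data were examined. It takes, per comparison, the 8 highest and the 8 lowest log2 ratios among called genes with a symbol whose 3 samples of one group all lay above the 3 of the other (the interaction without that last condition), up to 4 members with the lowest p of each list described, and a fixed set of hormone receptor, AMH, WNT and egg-white protein genes. The last class was read as secreted proteins of the egg white, without shell matrix genes, after the values had been seen. Some genes that the rule names are not reported here. A set of 29 gene lists on signalling, secretion, cell types and cell states was fixed beforehand, and 28 had at least 3 tested members. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with a correlation estimated from the data, and with fry, adjusted over lists within a comparison. Counts of called members are given over all genes and adjusted over the list alone. A term screen used the GO annotation of the table, for terms with 10 to 300 tested genes.

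Where a group had 0 counts for a gene, the ratio is a lower bound against 3 counts per library, and where it had 1 to 3 counts the ratio has an exact 95% interval. These bounds and intervals cover counting error only. Total counts ran from 13303458 to 23621985 per sample, and 625 genes had 0 counts in all samples. On simulated data with the spread of these samples and 200 genes changed 2-fold, the edgeR test recovered 81.5% of them for left minus right in oil, 79.5% for left minus right in EE, 83% and 84.5% for EE minus oil in left and right ducts, and 68% for the interaction. For 1.5-fold changes these shares were 38%, 47%, 56%, 50.5% and 8%.

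Threshold-free measures were the mean squared left minus right difference less its squared error, the correlation across genes of the EE effect in the 2 sides, and the difference at genes called with 1 oil replicate number left out and measured in the samples left out. Alternatives were DESeq2 1.42.0, limma on log2 FPKM with pseudocounts of 1, 0.1 and 0.5, other filters, scalings and weights, a replicate block, and leaving out each sample in turn. After the data had been seen, library-size scaling, a covariate for erythroid transcripts, leaving out haemoglobin genes, and leaving out 3 libraries with transcripts of other tissues were added. All samples and value columns of the table were used, and the numbers that mark replicates were not taken as pairs of ducts from the same embryo.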

Results

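Gene expression was measured by RNA sequencing in left and right Müllerian ducts of female quail embryos after exposure to sesame oil or to ethynylestradiol (EE), with 3 samples in each of the 4 groups. Total counts of replicates 1, 2 and 3 were 21218351, 23266636 and 13303458 in left oil ducts and 20693834, 21166087 and 20814970 in right oil ducts. In EE they were 21604903, 16101802 and 23621985 on the left and 22400127, 20171505 and 19713927 on the right. Of 16013 genes, 12113 passed the filter. Haemoglobin transcripts, from 7 genes, took 2.13% ± 0.834 (SD, n = 3) of the counts in left oil ducts, 8.76% ± 3.49 in right oil ducts, 1.68% ± 0.599 in left EE ducts and 3.83% ± 2.01 in right EE ducts.

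The comparison of left and right ducts in oil asks how far the sides differ without added oestrogen, since in female birds the left duct forms the oviduct and the right one regresses. Left ducts had more transcripts of dividing cells and of blood vessels, and right ducts had more of macrophages, matrix proteases and gonadotropin receptors. MKI67, a marker of dividing cells, stood at 256 CPM ± 24.9 (SD, n = 3) in left ducts and at 46.7 ± 5.28 in right ducts. WNT7A, a signal made by duct epithelium, stood at 143 ± 5.79 on the left and at 64.1 ± 3.72 on the right. MMP2, a protease of the extracellular matrix, stood at 308 ± 14.4 on the left and at 998 ± 59.5 on the right. FSHR, the receptor of follicle-stimulating hormone, stood at 0.543 ± 0.301 and 15.3 ± 4.02.

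With edgeR quasi-likelihood, 4422 genes (36.5%) differed between the sides in oil, 2232 higher on the left and 2190 higher on the right, and 1114 of them by at least 2-fold. Among the genes highest on the left were AHRR, a repressor of the aryl hydrocarbon receptor (log2 ratio 5.20 ± 0.42 SE, adjusted p = 1.64e-07), CLDN16, a tight junction protein (5.28 ± 0.92), GDF6, a ligand of the BMP family (4.46 ± 0.49), and TCF24, a transcription factor (3.89 ± 0.41). CFAP52, a protein of motile cilia, was 59.4-fold higher on the left (95% interval 10.3 to 2380), a call that limma on log2 FPKM did not make (adjusted p = 0.164). CALB2, which encodes calretinin, was 19.2-fold higher (6.25 to 95.5), with adjusted p = 0.0762 when oil_left 1, oil_right 1 and EE_right 1 were left out. FAM183A was at least 2.53-fold and GCNT3, a mucin-type glycosyltransferase, at least 1.83-fold higher, but limma did not call either (adjusted p = 0.0719 and 0.436). Among the genes highest on the right were FSHR (-4.74 ± 0.42), KCNMB4, a potassium channel subunit (-3.92 ± 0.31), CCDC3 (-3.85 ± 0.21, adjusted p = 2.96e-09), ELFN2 (-3.77 ± 0.45), ZP1, a protein of the egg coat (-3.64 ± 0.26), and AGTR1, an angiotensin receptor (-3.64 ± 0.50). In these 16 genes by rule all 3 samples of one side lay above the 3 of the other. The rest of them, the muscle genes TNNI2 (-4.21 ± 0.86) and CACNG1 (at least 27.7-fold lower on the left), had their highest counts in oil_right 1, without which TNNI2 stood at -2.59.

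All 28 genes of the proliferation list were higher in left oil ducts, and all 28 adjusted over the list alone (median log2 ratio 1.85, camera adjusted p = 1.01e-71, adjusted p = 0.00701 with an estimated correlation). They included MKI67 (2.45 ± 0.13), KIF11, a motor of the mitotic spindle (2.05 ± 0.10), CCNA2, a cyclin (2.03 ± 0.10), and NUSAP1 (2.11 ± 0.11). Of 28 endothelial genes, 20 were higher on the left and 1 on the right, the same numbers adjusted over the list alone (adjusted p = 0.0178 with an estimated correlation). They included FLT1, a receptor of VEGF (1.79 ± 0.15), TIE1 (1.36 ± 0.11), EMCN (1.35 ± 0.11) and SOX7 (1.17 ± 0.08). Of 18 macrophage and immune genes, 13 were higher on the right and 1 on the left, or 14 and 1 adjusted over the list alone (adjusted p = 0.0133 with an estimated correlation). C1QA, a complement component, stood at -3.12 ± 0.24, LAPTM5 at -2.32 ± 0.18 and CSF1R, a receptor of macrophage growth factors, at -1.20 ± 0.12. The 14 erythroid genes included 13 higher on the right, also 13 adjusted over the list alone (adjusted p = 0.516 with an estimated correlation). Haemoglobin alpha-A (LOC107320982) stood at -2.24 ± 0.43.

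Smooth muscle genes numbered 13 of 18 higher on the left and 0 lower, 16 adjusted over the list alone (camera adjusted p = 2.14e-05, adjusted p = 0.516 with an estimated correlation). ACTA2 (1.20 ± 0.17) and TAGLN (1.05 ± 0.16) were among them, and 4 of the list were called with an erythroid covariate. Of 22 epithelial genes 10 were higher on the left and 1 on the right, 12 and 2 adjusted over the list alone (adjusted p = 0.516 with an estimated correlation). CLDN1 stood at 0.83 ± 0.08 and ESRP2, a splicing factor of epithelia, at 0.93 ± 0.13, and 3 of the list were called higher with the covariate and 6 without oil_right 1. The genes of Müllerian duct formation included 6 higher and 3 lower on the left out of 17, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.104). Higher were WNT7A (1.16 ± 0.09, adjusted p = 8.15e-08), MSX2 (0.91 ± 0.09) and DACH2 (0.65 ± 0.09). WNT4, needed for duct formation, was higher on the right (-0.85 ± 0.14, adjusted p = 0.000186).

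In the hedgehog pathway 4 of 11 genes were higher on the left and 0 on the right, the same adjusted over the list alone (camera adjusted p = 0.196), with the pathway's target GLI1 at 1.82 ± 0.15. WNT pathway genes went both ways, 12 of 37 higher and 7 lower on the left, the same adjusted over the list alone (camera adjusted p = 0.355), with the WNT inhibitor NOTUM at 1.40 ± 0.12, WNT11 at -1.51 ± 0.14 and RSPO3 at -1.21 ± 0.11. BMP5 was higher on the right (-2.69 ± 0.15). Of 24 matrix proteases and their inhibitors, 9 were higher on the right and 5 on the left, 11 and 5 adjusted over the list alone (adjusted p = 0.0408 with an estimated correlation). MMP2 stood at -1.70 ± 0.09, ADAMTS9 at -1.51 ± 0.08 and ADAMTS1 at -1.47 ± 0.12. Collagen and matrix genes were 18 higher and 6 lower on the left of 37, 19 and 6 adjusted over the list alone (camera adjusted p = 0.034, adjusted p = 0.647 with an estimated correlation). ELN, elastin, stood at 0.86 ± 0.09 and COL5A1 at -1.05 ± 0.08.

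Retinoic acid genes on the right included DHRS3, a retinal reductase (-1.69 ± 0.09), and ALDH1A3, an enzyme of retinoic acid synthesis (-1.17 ± 0.08). In that list 6 of 14 were higher on the right and 3 on the left, the same adjusted over the list alone (camera adjusted p = 0.00637, adjusted p = 0.199 with an estimated correlation). The gonadal list had 4 of 7 genes higher on the right and 0 on the left, the same adjusted over the list alone (adjusted p = 0.0408 with an estimated correlation). They were FSHR, the luteinizing hormone receptor (LOC107310840, -4.50 ± 0.39), FST, follistatin (-2.17 ± 0.15), and SOX9 (-0.91 ± 0.26), and the last lost its call with the erythroid covariate. Of 20 steroid receptors and targets, 8 were higher on the right and 2 on the left, the same adjusted over the list alone (camera adjusted p = 0.00406, adjusted p = 0.199 with an estimated correlation). IGF1 stood at -1.92 ± 0.18, STC1 at -2.39 ± 0.21 and CTSD at -1.58 ± 0.12.

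The receptor genes ESR1 (0.16 ± 0.09, adjusted p = 0.19) and PGR (0.18 ± 0.17, adjusted p = 0.448) did not pass the test between the sides in oil, nor did AMH (-0.07 ± 0.27, adjusted p = 0.862), the hormone of duct regression, or its receptor AMHR2 (-0.62 ± 0.52, adjusted p = 0.383). The egg-white genes ovoinhibitor (LOC107320451, -2.02 ± 0.25), extracellular fatty acid-binding protein (LOC107321681, -2.24 ± 0.35) and CLU (-0.46 ± 0.11) were higher on the right, and CLU was not with limma (adjusted p = 0.0711) or the erythroid covariate (adjusted p = 0.237). Ovalbumin (LOC107309565, 1.06 ± 0.53), mucin-5B (LOC107314549, 1.46, adjusted p = 0.276), ovomucoid (LOC107320484, -1.87 ± 1.54) and TF (-1.05 ± 0.73) did not pass. ESR2, with 15 counts in all samples together, was below the filter.

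The groups did not overlap for 5746 genes (47.4%, against 10% by chance). The count fell to 1578 with an erythroid covariate, which ended the call of 30 of the 117 genes named and called in this comparison. Scaling by library size alone called 3749 genes higher and 1224 lower on the left, and under it the median ratio of all genes was 0.177.

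**Figure D1:**
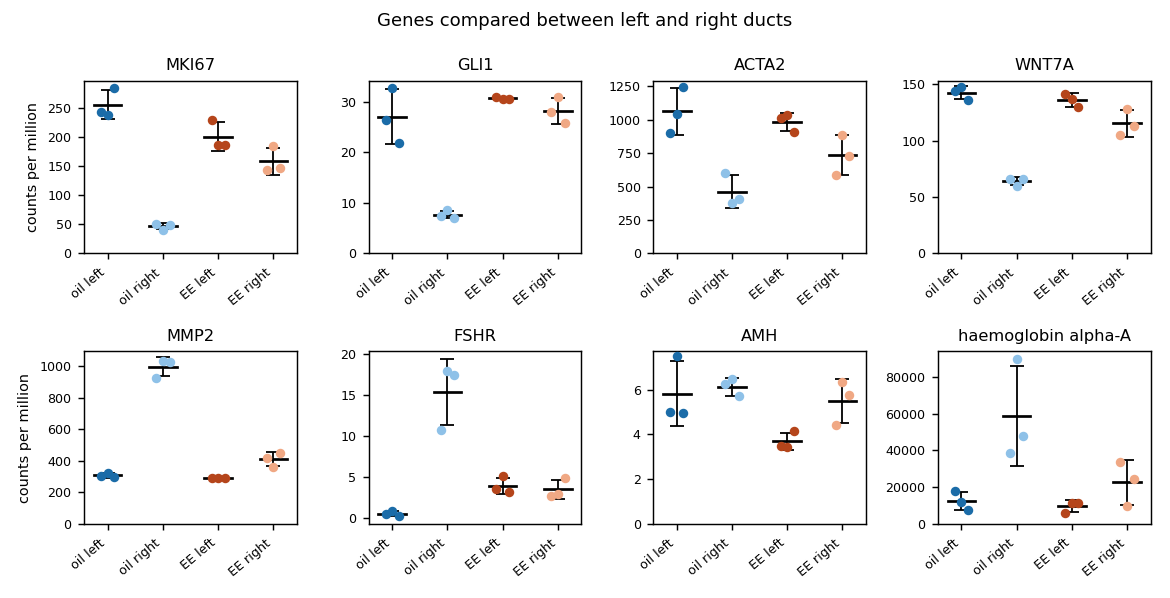
Expression in CPM of 8 genes in each sample (points), with group means (lines) and SD (bars, n = 3), for left and right ducts in oil and EE. MKI67 averaged 256 in left and 46.7 in right oil ducts, against 201 and 159 in EE ducts.

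The comparison of left and right ducts in EE asks whether the side difference is seen under exposure. It held 10 genes past the threshold, all higher on the right. CBLN1, a secreted synaptic protein, was at -1.74 ± 0.30 (SE, adjusted p = 0.042), OTOA, otoancorin, at -1.17 ± 0.12 (adjusted p = 0.000425), GAMT, an enzyme of creatine synthesis, at -1.09 ± 0.18, COL21A1 at -1.08 ± 0.14 and BMF, a regulator of apoptosis, at -0.97 ± 0.11. The transcription factor MAF (-0.88 ± 0.11), the protease MMP2 (-0.50 ± 0.09) and DHRS3 (-0.49 ± 0.08, adjusted p = 0.042) were also called, and all 10 were also higher on the right in oil. OTOA, COL21A1, BMF and MAF kept the call when any 1 sample was left out, and CBLN1, GAMT, MMP2 and DHRS3 lost it without oil_left 2, oil_left 3, oil_right 3, EE_right 1, EE_right 3 or any EE_left sample (adjusted p from 0.0525 to 0.26). CBLN1, GAMT and MMP2 also lost it without oil_left 1 and DHRS3 without oil_right 1. With a replicate block GAMT (adjusted p = 0.0872), MMP2 (0.0802) and DHRS3 (0.0868) were not called.

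Of the 28 proliferation genes 0 were called between the sides in EE over all genes, though 21 were higher on the left adjusted over the list alone (median 0.365, camera adjusted p = 4.67e-26, adjusted p = 0.157 with an estimated correlation). KIF11 stood at 0.40 ± 0.10. Erythroid genes likewise had 0 called over all genes and 10 of 14 higher on the right adjusted over the list alone (camera adjusted p = 4.68e-11, adjusted p = 0.346 with an estimated correlation). Macrophage genes had 0 called on either count (median -0.166, camera adjusted p = 0.00194, adjusted p = 0.157 with an estimated correlation), and so had smooth muscle genes (median 0.319, camera adjusted p = 3.22e-09, adjusted p = 0.426 with an estimated correlation). Endothelial genes had 0 called on either count as well (median 0.0923, camera adjusted p = 0.193). Collagen and matrix genes (0 of 37 called, 1 higher adjusted over the list alone, camera adjusted p = 8.77e-05, adjusted p = 0.786 with an estimated correlation) also passed at the preset correlation. So did retinoic acid genes (1 of 14 lower, 4 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0112, adjusted p = 0.346 with an estimated correlation). Matrix proteases had 1 of 24 lower, 2 adjusted over the list alone (camera adjusted p = 0.0132, adjusted p = 0.157 with an estimated correlation). ESR1, PGR, WNT7A, AMH and AMHR2 did not pass in EE, and WNT4 stood at -0.56 ± 0.14 (adjusted p = 0.215). At an unadjusted p under 0.05 there were 910 genes, DESeq2 called 80 and limma on log2 FPKM 0. Leaving out EE_right 2 gave 52 calls and leaving out any other sample 4 to 10, and 1531 genes (12.6%) had groups that did not overlap.

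**Figure D2:**
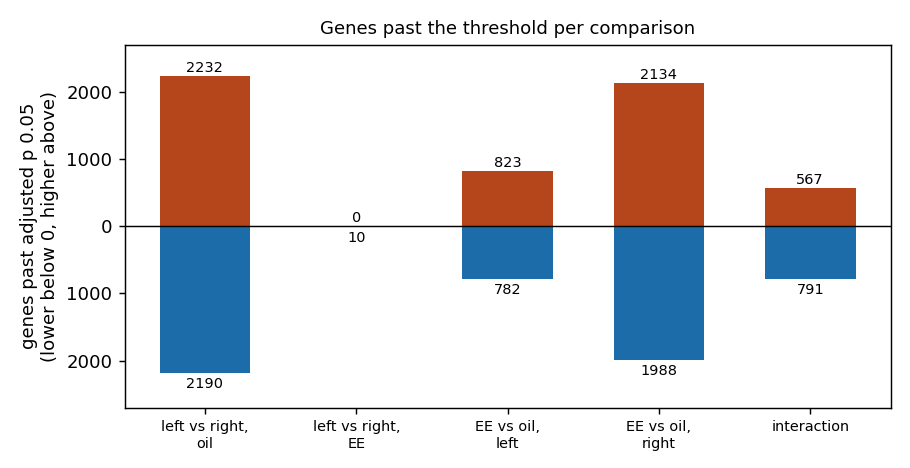
Number of genes past an adjusted p of 0.05 (edgeR quasi-likelihood) in each comparison, with genes of higher expression above 0 and of lower expression below 0. Left and right differed at 4422 genes in oil and at 10 in EE.

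EE was compared with oil in left ducts to see what the oestrogen changed on the side that develops. PGR, GREB1 and 6 of 13 egg-white and shell genes rose, and ESR1, an oestrogen receptor, fell. PGR, the progesterone receptor, rose from 60.9 CPM ± 13.3 (SD, n = 3) to 344 ± 11.9, GREB1, an oestrogen-responsive gene, from 9.73 ± 2.25 to 128 ± 16.2, and ESR1 fell from 960 ± 89.4 to 483 ± 39.7. Ovalbumin (LOC107309565) rose from 6.17 ± 1.69 to 119 ± 16.6. FOXL2, a transcription factor known from the ovary, rose from 0.665 ± 0.524 to 113 ± 3.81.

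In left ducts 1605 genes (13.3%) were called, 823 higher and 782 lower in EE, and 429 by at least 2-fold. TBX22, a T-box factor with 0 counts in oil, was at least 96.7-fold higher, RAB17, a trafficking protein of epithelia, at least 24.9-fold, SNTN, a protein of cilia, at least 14.1-fold and CCDC166 at least 9.95-fold. CCNO, which acts in the formation of multiciliated cells, was 148-fold higher (95% interval 50.3 to 719). FOXL2 rose by 7.55 ± 0.33 (log2 ratio with SE), ORM2 by 6.96 ± 1.01 and BCO2, a carotenoid-cleaving enzyme, by 6.93 ± 0.61. Among the lowest genes were MSX1, a homeobox factor (-4.52 ± 0.52), CLDN16 (-3.79 ± 0.79), ANGPTL5 (-3.62 ± 0.71), WNT9B (-3.59 ± 0.65), ANO4 (-3.24 ± 0.46), NTS, neurotensin (-2.69 ± 0.16), EMB (-2.58 ± 0.27) and SOX8 (-2.50 ± 0.71). The call of SOX8 was lost without oil_left 1 (adjusted p = 0.113), oil_left 2 (0.0526), EE_left 2 (0.0982) or EE_left 3 (0.0928).

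Of 13 egg-white and shell genes tested, 6 rose and 0 fell in left ducts, 7 and 0 adjusted over the list alone (camera adjusted p = 6.58e-10, adjusted p = 0.0358 with an estimated correlation). Ovomucoid (LOC107320484) rose by 9.13 ± 0.83, mucin-5B (LOC107314549) by 5.94 ± 0.57, ovoinhibitor (LOC107320451) by 5.29 ± 0.26, ovalbumin (LOC107309565) by 4.27 ± 0.45 and CLU by 0.80 ± 0.11, while TF stood at 0.66 ± 0.73 (adjusted p = 0.633). Extracellular fatty acid-binding protein (LOC107321681, 1.24 ± 0.35) lost its call without oil_left 1 (adjusted p = 0.117), oil_left 3 (0.0892), EE_left 1 (0.0836) or EE_left 2 (0.0884). Steroid receptors and targets had 6 of 20 higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.0138, adjusted p = 0.24 with an estimated correlation). GREB1 stood at 3.70 ± 0.23, PGR at 2.50 ± 0.18, IGF1 at 1.75 ± 0.18 and ESR1 at -0.99 ± 0.09. The gonadal list had 4 of 7 higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 7.15e-14, adjusted p = 0.00106 with an estimated correlation). Beside FOXL2 these were the luteinizing hormone receptor (LOC107310840, 3.47 ± 0.38), FSHR (2.77 ± 0.41) and INHBB (0.73 ± 0.19), the last not called without oil_left 3 (adjusted p = 0.071) or EE_left 3 (0.0757).

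Ciliated-cell genes had 11 of 22 higher and 0 lower in left EE ducts, 12 and 0 adjusted over the list alone (camera adjusted p = 1.08e-06, adjusted p = 0.177 with an estimated correlation). Without oil_left 1, oil_left 3 or EE_left 2 the ciliated-cell genes called were 7. DNAI2, an axonemal dynein, stood at 2.52 ± 0.54 and CFAP44 at 1.47 ± 0.32. Epithelial genes had 5 of 22 higher and 1 lower, 6 and 1 adjusted over the list alone (camera adjusted p = 0.0016, adjusted p = 0.296 with an estimated correlation). Without oil_left 3 or EE_left 1 the epithelial genes called higher were 3. EPCAM stood at 0.77 ± 0.10, ELF3 at 0.96 ± 0.13 and cadherin-1 (LOC107319509) at 0.81 ± 0.12. Collagen and matrix genes had 14 of 37 lower and 2 higher, 15 and 2 adjusted over the list alone (camera adjusted p = 1.57e-06, adjusted p = 0.413 with an estimated correlation). ELN stood at -0.89 ± 0.09, FBN2 at -0.93 ± 0.09 and COL4A5 at 1.83 ± 0.12. In the WNT list 11 of 37 were lower and 5 higher, 12 and 5 adjusted over the list alone (camera adjusted p = 0.00354, adjusted p = 0.154 with an estimated correlation). NOTUM stood at -1.26 ± 0.12, RSPO2 at -1.79 ± 0.22, DKK2 at -1.80 ± 0.25 and FZD10 at 1.05 ± 0.13.

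Among genes of duct formation 6 of 17 fell and 2 rose in left ducts, 7 and 3 adjusted over the list alone (camera adjusted p = 0.0765). FOXA2, a factor of gland epithelia, rose by 6.73 ± 0.51, and WNT4 fell by 0.86 with an SE of 0.14 (adjusted p = 0.000531). WNT7A (-0.07 ± 0.08, adjusted p = 0.664), AMH (-0.66 ± 0.27, adjusted p = 0.133) and AMHR2 (-1.29 ± 0.55, adjusted p = 0.146) did not pass. Of 28 proliferation genes 3 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 0.00211, adjusted p = 0.467 with an estimated correlation). They were PCNA (-0.30 ± 0.08), NUSAP1 (-0.37 ± 0.10) and KIF11 (-0.31 ± 0.09), each of them not called without oil_left 3, EE_left 1 or EE_left 3 (adjusted p from 0.0585 to 0.166). PCNA (0.0667) and KIF11 (0.0839) also lost the call without oil_left 2, and NUSAP1 (0.0509) and KIF11 (0.0695) without EE_left 2. With scaling by library size alone 0 of the 28 were called in left ducts by edgeR. Groups did not overlap for 3786 genes (31.3%).

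**Figure D3:**
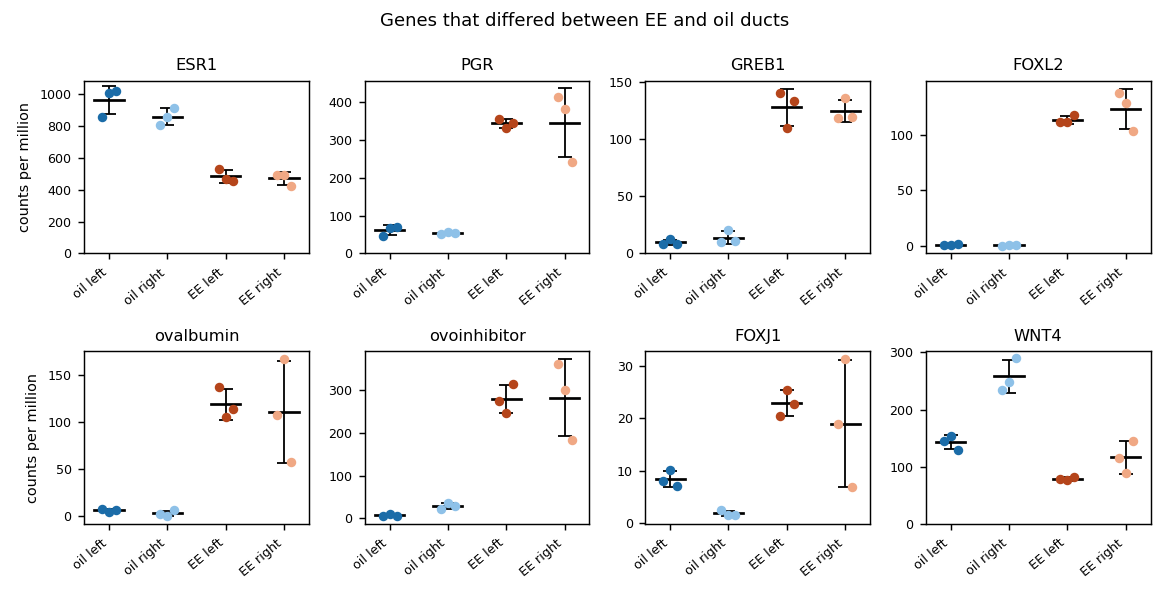
Expression in CPM of 8 genes in each sample (points), with group means (lines) and SD (bars, n = 3), in oil and EE ducts of both sides. PGR averaged 60.9 and 53.6 in left and right oil ducts and 344 and 345 in EE ducts.

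EE was compared with oil in right ducts to see what it changed on the side that regresses. GREB1, PGR and the lists of egg-white and ciliated-cell genes were higher as on the left, and cell division and vessel genes were higher as well. With an estimated correlation 0 of the 28 lists passed in this comparison (egg-white and ciliated-cell genes 0.179, proliferation 0.0621, endothelium 0.0841). MKI67 was at 159 CPM ± 23.1 (SD, n = 3) in right EE ducts against 46.7 ± 5.28 in right oil ducts, and MMP2 at 411 ± 46.8 against 998 ± 59.5. PGR was at 345 ± 90.4 against 53.6 ± 2.86, and FOXL2 at 123 ± 17.9 against 0.299 ± 0.284.

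In right ducts 4122 genes (34%) were called, 2134 higher and 1988 lower in EE, and 1048 by at least 2-fold. TBX22 was at least 99.4-fold higher, and the cilia genes ARMC4, SNTN and RSPH1 were at least 30-fold, 22.7-fold and 19.9-fold higher. FAM183A was at least 21.1-fold, GCNT3 at least 11.3-fold and PPIL6 at least 11.1-fold higher, and CFAP52 and CALB2 were 281-fold (95% interval 50 to 11100) and 32.9-fold (11 to 162) higher. FOXL2 rose by 8.66 ± 0.36 (log2, SE, adjusted p = 1.4e-09). Among the lowest genes were VWC2L (-3.98 ± 0.34), CEMIP, a hyaluronan-degrading protein (-3.83 ± 0.30), NXPH1 (-3.52 ± 0.38), LRRTM1 (-3.38 ± 0.48), ANO4 (-3.16 ± 0.44), RBFOX1, a splicing factor (-3.02 ± 0.24), and KCTD4 (-2.98 ± 0.39). CACNG1 was also among them (-5.26 ± 1.25), but DESeq2 did not call it (adjusted p = 0.151), and without EE_right 2 it had 0 counts in right EE ducts.

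All 28 proliferation genes rose in right ducts, all 28 adjusted over the list alone (median 1.34, camera adjusted p = 5.1e-39, adjusted p = 0.0621 with an estimated correlation). MKI67 stood at 1.76 ± 0.12, CCNA2 at 1.47 ± 0.10 and KIF11 at 1.34 ± 0.10. Endothelial genes had 21 of 28 higher and 3 lower, 22 and 3 adjusted over the list alone (camera adjusted p = 6.46e-08, adjusted p = 0.0841 with an estimated correlation). PLVAP stood at 1.54 ± 0.18, TIE1 at 1.20 ± 0.11 and SOX7 at 1.18 ± 0.08. Macrophage and immune genes had 10 of 18 lower and 1 higher, the same adjusted over the list alone (camera adjusted p = 3.23e-05, adjusted p = 0.0798 with an estimated correlation). C1QA stood at -1.69 ± 0.22 and LAPTM5 at -1.44 ± 0.17. Erythroid genes had 7 of 14 lower, 10 adjusted over the list alone, and 0 higher (camera adjusted p = 0.00749, adjusted p = 0.596 with an estimated correlation). Without oil_right 2 or EE_right 2 the number of erythroid genes called was 0. Haemoglobin alpha-A (LOC107320982) stood at -1.38 ± 0.42. Smooth muscle genes had 11 of 18 higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 0.00264, adjusted p = 0.596 with an estimated correlation). DES, desmin, stood at 1.09 ± 0.16 and MYL9 at 0.80 ± 0.15, and with the erythroid covariate 5 were higher and 1 lower.

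Ciliated-cell genes had 15 of 22 higher and 0 lower in right EE ducts, 16 and 0 adjusted over the list alone (camera adjusted p = 1.37e-06, adjusted p = 0.179 with an estimated correlation). FOXJ1, a regulator of motile cilia, stood at 3.39 ± 0.42. Epithelial genes had 12 of 22 higher and 0 lower, 13 and 0 adjusted over the list alone (camera adjusted p = 2.95e-05, adjusted p = 0.179 with an estimated correlation). Cadherin-1 (LOC107319509) stood at 1.24 ± 0.12 and EPCAM at 1.01 ± 0.10. Egg-white and shell genes had 7 of 13 higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.000894, adjusted p = 0.179 with an estimated correlation). Mucin-5B (LOC107314549) rose by 7.23 ± 0.66, ovomucoid (LOC107320484) by 6.35 ± 0.70, ovalbumin (LOC107309565) by 5.23 ± 0.49 and ovoinhibitor (LOC107320451) by 3.28 ± 0.23. TF was called at 2.12 ± 0.72 but stood at -0.31 without EE_right 1, and CLU (0.43 ± 0.11) was not called without that sample (adjusted p = 0.0522). Without oil_right 1 mucin-5B had 0 counts in right oil ducts, which leaves no ratio but a bound. Extracellular fatty acid-binding protein (LOC107321681) did not pass (-0.43 ± 0.33, adjusted p = 0.341).

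GREB1 (3.18 ± 0.22) and PGR (2.68 ± 0.18) rose in right ducts and ESR1 (-0.87 ± 0.09) and STC1 (-1.77 ± 0.20) fell. The list of steroid receptors and targets had 8 of 20 lower and 4 higher, 9 and 4 adjusted over the list alone (median -0.16, camera adjusted p = 0.393). The gonadal list had 3 of 7 higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.16). INHBB stood at 1.01 ± 0.19, FSHR at -2.14 ± 0.35 and FST at -2.10 ± 0.15. In the BMP list 8 of 24 fell and 4 rose, 9 and 4 adjusted over the list alone (camera adjusted p = 0.089). BMP5 stood at -2.60 ± 0.15 and BMPR1B at 2.12 ± 0.19. The WNT list had 12 of 37 lower and 9 higher, the same adjusted over the list alone (camera adjusted p = 0.454). WNT11 stood at -2.05 ± 0.14 and the stem cell marker LGR5 at 1.25 ± 0.10. Hedgehog genes had 4 of 11 higher and 3 lower, 4 and 4 adjusted over the list alone (camera adjusted p = 0.354). GLI1 stood at 1.88 ± 0.15 and the ligand IHH at 2.31 ± 0.33. Collagen and matrix genes had 17 of 37 lower and 8 higher, 19 and 10 adjusted over the list alone (camera adjusted p = 0.028, adjusted p = 0.596 with an estimated correlation). COL11A1 stood at -1.55 ± 0.08 and COL5A1 at -1.25 ± 0.08. FOXA2 (4.81 ± 0.41) and WNT7A (0.85 ± 0.09) rose, WNT4 (-1.15 ± 0.14) fell, and AMH (-0.15 ± 0.27, adjusted p = 0.697) and AMHR2 (-0.63 ± 0.52, adjusted p = 0.389) did not pass.

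With an erythroid covariate 2696 genes were called between right EE and right oil ducts. Scaling by library size alone called 3479 genes higher and 1113 lower, and under it the median ratio of all genes was 0.172. Groups did not overlap for 5580 genes (46.1%).

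**Figure D4:**
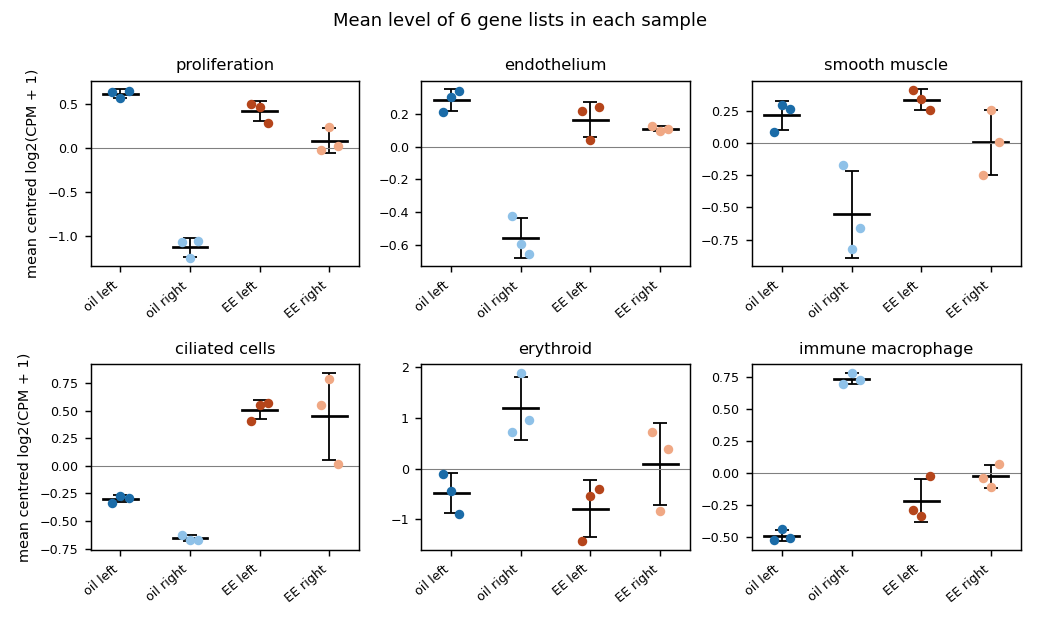
Mean centred log2(CPM + 1) of the genes of 6 lists in each sample (points), with group means (lines) and SD (bars, n = 3). The proliferation list averaged 0.618 in left and -1.12 in right oil ducts, and 0.42 and 0.0854 in EE ducts.

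On both sides together, 566 genes rose and 448 fell in EE, where independent calls would share 145 and 128, and 37 and 51 genes were called in opposite directions. Across genes, the EE effects of the sides correlated with r = 0.541 (Spearman 0.406), from comparisons that share no library, and genes are not independent replicates. FOXL2, TBX22, PGR, GREB1, ovalbumin and SNTN were among the genes higher on both sides, and ESR1, WNT4 and ANO4 among those lower on both.

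Of the genes higher on the left in oil, such as MKI67, GLI1 and WNT7A, 1350 (60.5%) also rose in right ducts with EE, where independent calls would share 393. Of those higher on the right, such as BMP5, MMP2 and FST, 1305 (59.6%) fell, against 359. Both comparisons use the right oil samples, and simulations without any change gave r = 0.507 across genes against 0.617 measured, a covariance of 0.0306 against 0.31, and 0 shared calls. The 0 shared calls follow from a setting in which no gene differs, and do not measure the overlap that shared samples add. Part of the excess may come from these shared samples. In a check without shared right oil samples, genes were called between the oil sides with 1 replicate number left out. Right EE ducts were then compared with the right oil sample left out. Towards the level of left oil ducts, the median difference was 0.43 ± 0.0811 (log2, SD of 3 rounds that share the EE samples), from 0.347 to 0.509. This argues against shared samples as the whole source of the overlap. In left ducts, 310 of the genes higher on the left in oil fell with EE (144 by independent calls) and 171 rose (152). Of those higher on the right in oil, 205 rose in left ducts (149) and 157 fell (141). Here the left oil samples are shared, and the covariance was -0.0941 against -0.0299 in the simulations. No check without shared left oil samples was made.

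The interaction tests directly whether the left-right difference itself differed between EE and oil. The differences in cell division, vessel, macrophage and gonadotropin receptor genes were smaller in EE. MKI67 had a left minus right log2 ratio lower by 2.11 ± 0.17 (SE) in EE than in oil (interaction -2.11, adjusted p = 5.36e-06), and FSHR had an interaction of 4.91 ± 0.54 (adjusted p = 2.78e-05), with 3.94 CPM ± 0.989 (SD, n = 3) in left and 3.48 ± 1.19 in right EE ducts. The test called 1358 genes (11.2%), 567 higher and 791 lower, and 535 by at least 2-fold.

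High interactions beside that of FSHR included those of VWC2L (3.86 ± 0.46), ZP1 (3.55 ± 0.33), LRRTM1 (3.38 ± 0.67), KCNMB4 (3.21 ± 0.41) and ELFN2 (3.12 ± 0.60), and low ones included those of GDF6 (-4.02 ± 0.62), TCF24 (-3.88 ± 0.52), DMRT2 (-3.70 ± 0.98), AHRR (-3.34 ± 0.55) and RP1 (-3.32 ± 0.86). CACNG1 (adjusted p = 0.0341), FAM183A (0.0211), CFAP52 (0.00729) and CALB2 (0.00836) were called with 0 to 3 counts in a group. The call of DMRT2 was lost without oil_left 3, oil_right 3, EE_left 2, EE_left 3 or EE_right 3 (adjusted p from 0.0511 to 0.065), that of RP1 without oil_left 2 (0.0573) and with limma (0.753), and that of FAM183A without oil_left 2 (0.0661) and with limma (0.201). AHRR was not called with limma at a pseudocount of 0.1 (adjusted p = 0.058), CFAP52 with limma at 1 (0.584) or without oil_left 1, oil_right 1 and EE_right 1 together (0.0599), and CALB2 without these 3 libraries (0.0734). TNNI2 (3.98 ± 1.17, adjusted p = 0.0372) was not called without oil_right 1 (adjusted p = 0.133), oil_left 2, oil_left 3, EE_left 2, EE_left 3 or any EE_right sample (0.05 to 0.11), nor CACNG1 without EE_left 3 (adjusted p = 1), any left oil sample, oil_right 1, EE_right 1 or EE_right 3 (0.0527 to 0.0647). Nor was TNNI2 called with limma (adjusted p = 0.12), or CACNG1 with DESeq2 (0.158) or a replicate block (0.0576).

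All 28 proliferation genes had a lower interaction, all 28 adjusted over the list alone (median -1.52, camera adjusted p = 8.55e-71, adjusted p = 0.00784 with an estimated correlation). KIF11 (-1.65 ± 0.14) and NUSAP1 (-1.70 ± 0.15) were among them. Endothelial genes had 17 of 28 lower and 1 higher, 19 and 1 adjusted over the list alone (adjusted p = 0.0112 with an estimated correlation). PLVAP stood at -1.99 ± 0.24 and TIE1 at -1.39 ± 0.15. Macrophage and immune genes had 9 of 18 higher and 1 lower, 12 and 1 adjusted over the list alone (adjusted p = 0.0112 with an estimated correlation). C1QA stood at 2.42 ± 0.33 and LAPTM5 at 1.99 ± 0.25. The gonadal list had 3 of 7 higher and 0 lower, the same adjusted over the list alone (adjusted p = 0.0169 with an estimated correlation). They were FSHR, the luteinizing hormone receptor (LOC107310840, 4.44 ± 0.50) and FST (1.80 ± 0.21). Steroid receptors and targets had 4 of 20 higher and 0 lower, 6 and 1 adjusted over the list alone (camera adjusted p = 0.00317, adjusted p = 0.172 with an estimated correlation). CTSD stood at 1.41 ± 0.16 and IGF1 at 1.65 ± 0.24. Matrix proteases had 7 of 24 higher and 1 lower, 8 and 3 adjusted over the list alone (camera adjusted p = 0.0133, adjusted p = 0.0781 with an estimated correlation). MMP2 stood at 1.20 ± 0.12 and ADAMTS9 at 1.10 ± 0.11.

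WNT7A (-0.92 ± 0.12), MSX2 (-0.64 ± 0.12), DACH2 (-0.65 ± 0.13), NOTUM (-1.42 ± 0.17) and GLI1 (-1.70 ± 0.21) had lower interactions, and BMP5 (2.10 ± 0.20), DHRS3 (1.20 ± 0.12), ovoinhibitor (LOC107320451, adjusted p = 0.000647) and WNT11 (1.23 ± 0.20) higher ones. ESR1 (-0.13 ± 0.13, adjusted p = 0.62), PGR (-0.18 ± 0.24, adjusted p = 0.696), WNT4 (0.29 ± 0.19, adjusted p = 0.403), AMH (-0.50 ± 0.38, adjusted p = 0.465) and ovalbumin (LOC107309565, -0.96 ± 0.65, adjusted p = 0.402) did not pass. Scaling by library size alone gave 309 higher and 1208 lower interactions, with a median of all genes at -0.147.

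Genes called between the sides in oil with 1 replicate number left out (mean 3350) were measured in the oil samples left out and in the EE samples. Left minus right was taken between samples of the same number, which are not known pairs. The median was 0.595 ± 0.102 (log2, SD of 3 rounds) in oil and 0.137 ± 0.0746 (SD over the 3 EE numbers) in EE. The sign was the same for 93.7% of the genes in oil, from 1 sample per side. In EE it was the same for 85.7%, from means of 3 samples per side, so these shares are unlike measures. The mean squared left-right difference less its error was 0.239 in oil and 0.00909 in EE. Its ratio of 0.0381 ranged from -0.00131 without EE_right 1 to 0.125 without EE_right 2. On the first principal component, which held 44.2% of the variance, left and right oil ducts averaged -2.71 ± 3.73 and -51.3 ± 4.23 (SD, n = 3) and left and right EE ducts 33.1 ± 2.45 and 20.9 ± 9.54.

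**Figure D5:**
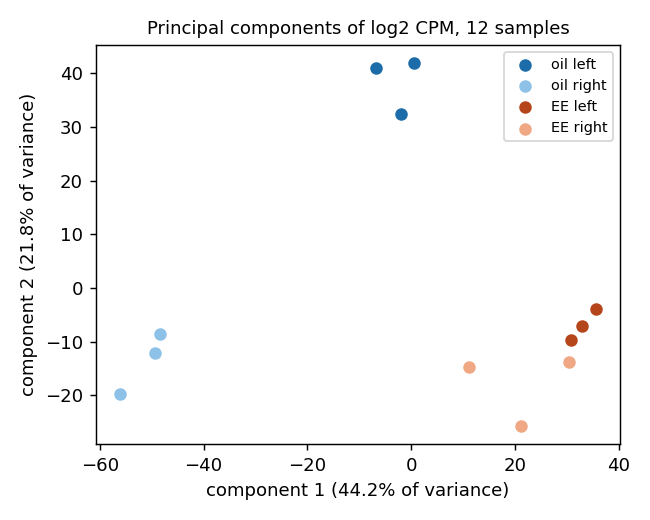
Samples (points) on the first (44.2% of variance) and second (21.8%) principal components of log2 CPM over the tested genes, coloured by group. Left oil ducts lay at 38.4 ± 5.29 on the second component and the other groups between -18.1 and -6.88 on average.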

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

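The tests of replicate spread, of blood content and of muscle tissue were chosen after the results had been seen. The counts of other splits of the samples were planned.

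The left minus right difference differed between EE and oil for 1358 genes by the interaction test, and this difference of effects is what singled out the results given here. Higher interactions were those of FSHR (4.91), TNNI2 (3.98), VWC2L (3.86), ZP1 (3.55), LRRTM1 (3.38), KCNMB4 (3.21) and ELFN2 (3.12), and CACNG1 was also higher (adjusted p = 0.0341). Lower interactions were those of GDF6 (-4.02), TCF24 (-3.88), DMRT2 (-3.70), AHRR (-3.34) and RP1 (-3.32), and FAM183A (adjusted p = 0.0211), CFAP52 (0.00729) and CALB2 (0.00836) were lower as well. Among the gene lists, proliferation (median -1.52) and endothelial genes (-0.959) had lower interactions, and macrophage and immune genes (1.16) and the gonadal list (0.662) higher ones. TNNI2, CACNG1, DMRT2, FAM183A, CFAP52, CALB2, AHRR and RP1 lost the call under at least 1 alternative, while FSHR, VWC2L, ZP1, LRRTM1, KCNMB4, ELFN2, GDF6 and TCF24 kept it under each alternative that tested them. The stricter filter did not test FSHR, VWC2L, ZP1, LRRTM1, ELFN2 and GDF6.

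The smaller left-right difference in EE, where 10 genes passed against 4422 in oil, was set against chance, noise and blood. Chance is not excluded by regrouping, since 9 of 100 splits of the samples, the real one included, gave at least 1358 interaction calls (highest of the others 3778). These 9 all kept the left and right oil samples whole, the other 91 gave 0 calls, and a split that calls several times the real number points to a structure of the samples, here the groups themselves. A larger replicate spread of single genes in EE is argued against by that spread itself. The median within-group SD of log2 CPM was 0.135 and 0.141 in left and right EE ducts, against 0.146 and 0.149 in oil. This median does not cover spread shared by many genes. On the first principal component the SD was 2.45 and 9.54 in left and right EE ducts, and 3.73 and 4.23 in oil. Without EE_right 2, 52 genes were called between the sides in EE. At genes picked in oil, the EE difference was 0.23 of that in the oil samples left out. The SD of that ratio, 0.0402, is over rounds that share the EE samples, so it holds no EE replicate error. By EE replicate number the median difference ran from 0.0457 to 0.199, against 0.478 to 0.664 in the oil samples left out. With an erythroid covariate 1033 of the interaction calls were kept, so the level of erythroid transcripts, as fitted, did not account for these. That covariate comes from the same samples and moves with the groups, so it does not decide whether blood is the whole cause. Open are blood content, the EE exposure itself, which is the biological difference in the design, and a difference in dissection or stage between groups, which was not tested.

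Skeletal muscle genes stood higher in right than in left oil ducts, 5 of 8 past the threshold with a list median of -3.08. Muscle tissue in oil_right 1 is a candidate source, since MYL1 had 2254 counts there and at most 123 in any other sample. Without that sample the list median was -0.21, with 1 gene higher and 1 lower past the threshold. TNNI2 (-2.59, adjusted p = 0.0117) stayed lower on the left without it, which that source leaves open. No biological explanation was tested for this pattern.

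For each of the 4 comparisons of 2 groups, the real split was 1 of 10, too few for a share under 0.05. The real splits called 4422 genes for the sides in oil, 10 for the sides in EE, 1605 for EE in left ducts and 4122 for EE in right ducts, and the highest of the other splits called 0 in each.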

How the results depend on the processing

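Scaling by library size alone, an erythroid covariate, leaving out the haemoglobin genes and leaving out 3 libraries (oil_left 1, oil_right 1, EE_right 1) were alternatives chosen after seeing the data. The others were chosen before the data were examined.

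The counts of called genes moved by less than 1.5 times under most alternatives. With DESeq2 they were 4698 for the sides in oil, 1961 for EE in left ducts, 4412 for EE in right ducts and 1791 for the interaction, and with a replicate block 4390, 14 for the sides in EE, 1564, 4035 and 1373. Leaving out 1 sample gave 3578 to 4416, 1211 to 1678, 3244 to 4184 and 1015 to 1467, and leaving out the 3 libraries 3573, 1272, 3364 and 1228. A minimum of 2-fold, which only removes calls, left 1114, 4 for the sides in EE, 429, 1048 and 535. Directions shifted with limma on log2 FPKM (pseudocount 1), which has no TMM scaling. It called 3603 genes higher and 1193 lower for the sides in oil (median of all genes 0.156). For EE in right ducts it called 3440 and 1046 (median 0.153), and for the interaction 292 and 1017 (median -0.127). With quantile normalization limma called 2194 higher and 1942 lower for the sides in oil. The erythroid covariate gave 1578 for the sides in oil and 2696 for EE in right ducts, and it moves with the groups, so the cause was not tested. The 10 genes of the sides in EE became 0 with limma on log2 FPKM at pseudocounts of 1 and 0.1, 2 at 0.5, 1 without a trend, 6 with quantile normalization, 80 with DESeq2, 4 in a fit of the groups compared alone, 5 with the erythroid covariate, 6 without the 3 libraries and 4 to 52 without 1 sample. The cause was not tested, except that a fit of fewer samples has fewer degrees of freedom.

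DESeq2 gave no adjusted p for TF in any comparison, so TF has no value there. The stricter filter left out genes of low expression, such as FSHR and GDF6, which have no value under it. Of the named genes called for the sides in oil, 87 of 117 kept the call with the erythroid covariate, 30 lost it, and 107 of 117 kept it without the 3 libraries. Without these libraries 5 of 8 named genes kept the call for the sides in EE, 92 of 95 for EE in left ducts, 112 of 120 for EE in right ducts and 71 of 85 for the interaction, where 77 kept it with the covariate. Correlations of replicates with the same number across the sides were 0.0411, 0.12 and 0.136 in oil and -0.0364, 0.037 and 0.0875 in EE, which gives no sign that numbers pair the ducts.

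Of the 28 lists, camera at the preset correlation called 11 for the sides in oil, 7 for the sides in EE, 13 for EE in left ducts, 11 for EE in right ducts and 9 for the interaction. With an estimated correlation these were 5, 0, 2, 0 and 4, and with fry, which does not compare a list with other genes, 20 for the sides in oil, 0 for the sides in EE and 19 for EE in right ducts. GO terms fell from 24, 9, 10 and 25 (the sides in oil, the sides in EE, EE in right ducts and the interaction) to 0 with an estimated correlation. The preset test assumes a correlation of 0.01 among members of a list, and the other test estimates it from these samples. Where members are correlated above 0.01, the adjusted p-values of camera at the preset are too low.

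The side variance in oil (0.239) was 0.356 at a pseudocount of 0.1, 0.284 at 0.5, 0.192 without a filter, 0.221 with median-of-ratios scaling, 0.21 with quantile normalization and 0.208 to 0.263 without 1 sample. In EE it was -0.000312 to 0.0299 without 1 sample, and the ratio -0.00131 to 0.125. The correlation of the EE effects of the sides on log2 FPKM (0.537) was 0.564 at a pseudocount of 0.1, 0.514 without a filter and 0.504 to 0.551 without 1 sample, and Spearman's (0.419) was 0.395 without a filter and 0.38 to 0.442. Their covariance (0.0975) was 0.188 and 0.126 at pseudocounts of 0.1 and 0.5, 0.08 without a filter, 0.0881 with the stricter filter and 0.0918 to 0.107. With genes called at an adjusted p under 0.01, the held-out oil difference (0.595) was 0.783. The cause was not tested.

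Genes that changed sign had not passed the test, apart from TF in right ducts, and the cause was not tested. Between the sides in oil, AMH was 0.0568 with limma with and without a trend, 0.0772 and 0.0666 at pseudocounts of 0.1 and 0.5, 0.12 with array weights, 0.114 with library size alone, 0.0501 without the 3 libraries and -0.300 to 0.0361 without 1 sample, and with the erythroid covariate AMHR2 was 0.796 and TF 0.492. Between the sides in EE, in the same order, PGR was 0.0591, 0.0603, 0.0598, 0.0636, 0.0245, 0.138 and -0.204 to 0.143, with 0.0305 by quantile normalization and 0.0312 with the replicate block. Ovoinhibitor (LOC107320451) was 0.0596, 0.0602, 0.0599, 0.0458, 0.015, 0.201 and -0.246 to 0.206, with 0.019 by quantile normalization, 0.028 with the block and 0.0793 with the covariate. There the covariate gave -0.0393 for ESR1 (-0.0301 to 0.0844 without 1 sample), -0.277 for ovalbumin (LOC107309565, -0.202 to 0.527) and -0.0116 for mucin-5B (LOC107314549, -0.194 to 0.474), and CLU was 0.0700 without the 3 libraries (-0.203 to 0.0756). In right ducts, AMH was 0.00475 with limma with and without a trend, 0.000888 and 0.00355 at pseudocounts of 0.1 and 0.5 and 0.0202 with library size alone, AMHR2 was 0.215 with the covariate, and TF was -0.475 without the 3 libraries and -0.311 to 2.62 without 1 sample. In the interaction TF was 0.937 and -1.96 to 0.966, and mucin-5B was 0.164 with limma with and without a trend, 0.0508 and 0.192 at pseudocounts of 0.1 and 0.5, 0.191 with quantile normalization and 0.181 with array weights.

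Depth limits the genes with few counts in a group, whose ratios are bounds, and those below the filter, such as ESR2.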

Other observations

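All values in this part were picked from the results after they had been seen, except that the gene lists and the rule for named genes were fixed before the data were examined.

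Interferon response genes were not described above. In left ducts 3 of 15 rose with EE and 0 fell, 4 and 0 adjusted over the list alone (camera adjusted p = 0.029, adjusted p = 0.154 with an estimated correlation): IRF7, a regulator of interferon genes (1.22 ± 0.18), an interferon-induced GTP-binding protein (LOC107323611, 1.38 ± 0.26) and PARP14 (1.03 ± 0.23). In right ducts 2 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.526), with the GTP-binding protein at 2.15 ± 0.28. Of the targets of mechanical and growth signals, CCN2 was higher on the left in oil (2.92 ± 0.21) and fell with EE in left ducts (-1.52 ± 0.20), and the immediate-early genes JUN (-1.09 ± 0.09) and EGR1 (-0.90 ± 0.14) were higher on the right in oil. In the list of stress and immediate-early genes 7 of 23 were higher and 5 lower on the left in oil, the same adjusted over the list alone (camera adjusted p = 0.869). With EE in left ducts 3 of them rose and 4 fell, 4 and 4 adjusted over the list alone (camera adjusted p = 0.498).

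Lysosomal genes differed between the sides in oil, with CTSA, a carboxypeptidase of lysosomes, at -1.23 ± 0.09 and NPC2, a cholesterol carrier, at -0.91 ± 0.12, all higher on the right. In the list of apoptosis and lysosome genes 12 of 26 were higher on the right and 8 on the left, the same adjusted over the list alone (camera adjusted p = 0.0602). HOX genes had 2 of 32 higher on the right in oil and 0 on the left, 0 adjusted over the list alone (camera adjusted p = 0.669), and with EE 8 fell and 3 rose in left ducts, 10 and 4 adjusted over the list alone (camera adjusted p = 0.0167, adjusted p = 0.422 with an estimated correlation), with HOXD8 at 1.28 ± 0.21 and HOXA11 at -0.76 ± 0.16. Of 5 genes of left-right patterning tested in oil, SNAI1 was higher on the left (0.86 ± 0.13) and CITED2 (-0.75 ± 0.11) and PKD2 (-0.31 ± 0.08) on the right, the same numbers adjusted over the list alone (camera adjusted p = 0.771).

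FOXL2 had 1863 to 3055 counts in the EE samples and 0 to 17 in the oil samples. In the same EE samples, genes known from the ovary and its germ cells reached at most 3 counts for STAR, 27 for 3-beta-hydroxysteroid dehydrogenase (LOC107319373), 15 for INHA, 14 for NR5A1, 9 for DDX4 and 4 for DAZL. Together they came to between 0.069% and 1.13% of the FOXL2 counts of an EE sample. In the oil samples their highest counts were 9, 3, 0, 8, 0 and 0, in the same order. Other genes known from these tissues were higher in EE. Of 5 germ-cell genes tested, 1 rose in left and 3 in right ducts and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.425 and 0.0619). PIWIL1 stood at 2.025 to 8.435 CPM in EE samples and at 0 to 1.153 in oil samples. The gonadal list had 4 of 7 higher and 0 lower in left ducts, and 3 higher and 3 lower in right ducts.

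In 3 samples, some transcripts stood far above their counts in every other sample. In oil_right 1, MYL1 had 2254 counts, TNNC2 1515 and TNNT3 980, all genes of skeletal muscle. In EE_right 1, TF, which is also in the egg-white list, had 11448 counts, with at most 1130 in any other sample. Gallinacin-10-like (LOC116653208) had 2872 counts in EE_right 1 and 965 in EE_right 3. Avidin-like (LOC107305801) had 179 and 39, so such transcripts were not confined to 1 right EE sample. In oil_left 1, keratin-associated protein 6-1-like (LOC107324400) had 688 counts and keratin type I cytoskeletal 19-like (LOC107325272) 574.

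The screen of 399 GO terms had 24 terms past the threshold for the sides in oil, 9 for the sides in EE, 0 for EE in left ducts, 10 for EE in right ducts and 25 for the interaction at the preset correlation, led in oil by spindle microtubule (camera adjusted p = 2.84e-08) and cell division (1.47e-06), and 0 in each with an estimated correlation (lowest adjusted p = 0.32).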
